A study of Danio rerio with 12 samples.

How the data were processed

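RNA from the trunk of zebrafish embryos injected with a morpholino against grnA (granulin a, which encodes the secreted growth factor progranulin A) was set against RNA from untreated wild-type embryos of the same age on 2-colour Agilent 44K arrays, per the labels. A morpholino is an antisense oligomer that blocks the translation or the splicing of its target; which of these was meant here is not given in the sources used here. The morphant RNA carried Cy5 (red) and the wild-type RNA Cy3 (green) on all 12 arrays, so the dye was never swapped. Every ratio below is morphant over wild type, that is Cy5 over Cy3. The ages were 16, 24, 48 and 72 hours post-fertilisation (hpf), with 3 biological replicates each, and the series text gives 200 embryos per group.

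The scanner files hold, per the file headers, the median intensity of each spot and of its local background in both channels, as extracted by Agilent Feature Extraction 10.5.1.1, which the submitters' processing notes also name. The same deposited files hold a log10 ratio of red over green that Feature Extraction computed after its own background and dye correction, with the value 0 where both channels were too dim. The series' value table, deposited by the authors, holds that same log10 ratio: each column equalled the ratio of 1 scanner file on 100 percent of spots within a relative tolerance of 0.006, and that of the next best file on at most 24 percent. The median of every value-table column was 0. The sources used here give no centring beyond that of Feature Extraction. The array design refers to genome build danRer5. No coordinate is used here.

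The deposited records disagree on which scanner file belongs to which sample. For 10 of the 12 arrays the scanner file attached to a sample differs from the file that equals the value-table column carrying that sample's name. The attached files run through the 3 slides one after another in sample order, whereas the value table puts the 4 ages of a replicate on the same slide. The files were linked to samples through the value table, and every count was recomputed with the files as attached. The choice of link was made after seeing the data. In the wild-type channel the median within-age SD over genes was 0.262 on the log2 scale with the value table's link and 0.468 with the attached files. The median log2 level of the somitogenesis list in wild type was 11.37 ± 0.35, 9.78 ± 0.04, 7.68 ± 0.18 and 7.53 ± 0.33 at 16, 24, 48 and 72 hpf (SD, n = 3) with the value table's link, against 9.65 ± 1.87, 9.63 ± 2.10, 8.90 ± 1.81 and 8.18 ± 1.42 with the attached files. By the value table's link the attached files of each age mix ages, and the wider wild-type spread argues against the attached link. Calls lost with the files as attached can therefore come from mixed ages. With the link used here slide and replicate number are the same thing, so the replicate block is also the slide block.

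In R 4.3.3 with limma 3.58.1, the background was corrected with normexp (offset 50) on all spots. The design fixed before the data were examined named mean signals; the files hold median signals, which were used. Control spots had weight 0 and outlier-flagged spots were left out. Each array was normalised by loess, with no scaling between arrays, and spots of the same probe were averaged. Of 43603 probes, the 35932 that stood well above background in either channel on at least 3 of the 12 arrays were tested. Probes were named by matching unversioned accessions to a RefSeq gene table. This gave a symbol to 16770 probes and 16039 of those tested, which stand for 11175 genes, and 2434 of 19195 RefSeq probes had no match. All other probes, among them 5314 with Ensembl transcript accessions, stay unnamed here. For values per gene the probe with the highest mean intensity was taken.

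A linear model with 1 mean per age was fitted to all 12 arrays and tested with eBayes, so the 4 ages share an estimate of the spread with 8 residual degrees of freedom. Each mean was tested against 0, the 3 neighbouring differences were tested 1 by 1, and a moderated F test took them together. The Benjamini-Hochberg adjusted p had to be under 0.05, and adjusted p-values in the text are from limma. A dye effect that is the same on all arrays would pass as a change at every age and cancels only in differences between ages. The 3 arrays of an age limit the precision. Gene lists, 32 in number and fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 wherever at least 4 members were measured. That made 31 lists and 124 list and age tests, adjusted together. Camera with an estimated correlation and fry were alternatives.

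Named genes follow a rule also fixed before the data were examined. At each age these were the 8 largest rises and 8 largest falls past the threshold that went the same way on all 3 arrays, stood well above background in at least 1 channel on all 3 and have a gene name other than a clone or locus name. The granulin genes were always named. Results of 2 genes that the rule takes are not reported here. Up to 2 rises and 2 falls past the threshold were taken from each list. For calls shared by all 4 ages up to 5 rises and 5 falls were taken. The rule for differences between ages named none, as no probe passed the F test. The correlation of the morphant ratio with the wild-type change with age used the Cy3 channel after quantile normalisation of the average intensities, with no array on both sides.

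Because the slides hold all 4 ages, counts with the slide as a block are given beside the main ones. The slides are also the replicates, and a fixed block takes the spread between them out of the error of an age mean. At 16 hpf the median SE was 0.126 without and 0.104 with the block. Block counts for an age against 0 therefore hold for these 3 slides only and are no stricter check. Within a slide each age has 1 array, so a slide alone gives values and no test. Alternatives changed the background correction, offset, normalisation, filter, unit of test, variance model, array weights, block, threshold and arrays used. Median centring in place of loess leaves the trend along intensity in and raised the top intensity quintile by a median of 0.62. Values and list medians that turn above 0 under it therefore do not test a fall. The scripts were tested on simulated data with the real probes' spread and 200 changed probes at 48 hpf among 35932. They recovered 28.4 percent of the probes changed by a log2 ratio of 0.5, 74.6 percent at 1 and 92.4 percent at 2, with 10 false calls. A list shifted by 0.5 in the same simulation was called, and no other list was. The simulated noise was independent between probes and arrays, without a slide effect. It thus says nothing on false calls where genes or arrays are correlated.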

Results

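The series asked how gene expression in the trunk of zebrafish embryos differs after knockdown of grnA, across the ages from somite formation to the hatching larva. It holds 12 arrays, each setting RNA of grnA morphants against RNA of wild-type embryos of the same age, with 3 replicates at 16, 24, 48 and 72 hpf. Between 69.7 and 81.5 percent of the probes stood well above background in the morphant channel and between 48.5 and 77.4 percent in the wild-type channel. The lowest shares in both channels were on replicate 1 arrays, whose median wild-type signal was 72 to 90.5, against 95 to 143 on the others. Replicates differed widely. The correlation of log ratios across probes between arrays of the same age ran from -0.22 for replicates 2 and 3 at 16 hpf to 0.69 for replicates 1 and 3 at 48 hpf. Deposited records disagree on the file of 10 arrays, so each count at an age is given beside the count with the files as attached to the samples.

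The targeted gene, grna, was measured by 1 probe well above background on all arrays, and with the link used here it did not pass the test at any age. With the files as attached it was lower at 72 hpf, at -1.03 (adjusted p = 0.018), and did not pass at the other ages. By the value table's link those files are the replicate 3 arrays of 24, 48 and 72 hpf, so the value does not show a fall at 72 hpf. With the link used here its log2 ratio was -0.09 ± 0.54 at 16 hpf, 0.00 ± 0.41 at 24 hpf, -0.58 ± 0.89 at 48 hpf and -0.30 ± 0.74 at 72 hpf (SD, n = 3), with limma adjusted p of 0.999, 0.999, 0.375 and 0.669. The lowest values came from replicate 3, at -1.56 at 48 hpf and -1.15 at 72 hpf, while replicate 2 stood at 0.19 and 0.16. The paralogue grnb had log2 ratios of 0.14, 0.08, 0.05 and -0.26 at the 4 ages, and grna.2, a short granulin, had 0.00, 0.00, 0.13 and -0.35. The grna.2 probe was near background at the younger ages, standing above it in wild type on 1 of 3 arrays at 16 hpf and 2 of 3 at 24 hpf. Neither gene passed the test. These transcript levels neither bear out nor contradict the labels, since a morpholino that blocks translation leaves the transcript in place.

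**Figure D1:**
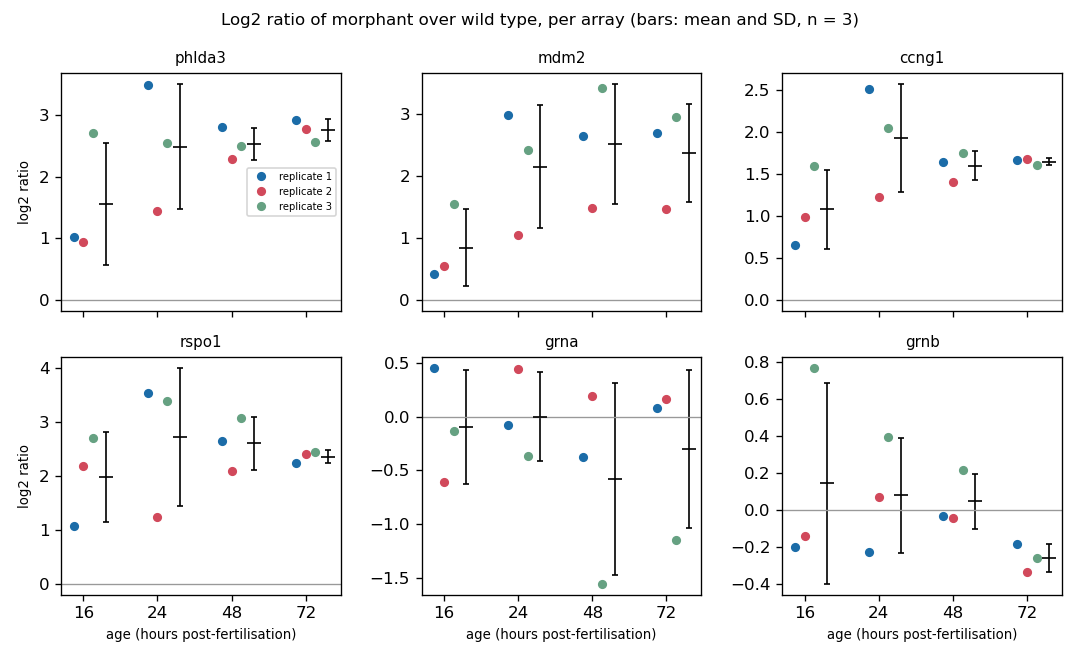
Log2 ratio of morphant over wild type on each array (vertical axis) against age in hpf (horizontal axis) for phlda3, mdm2, ccng1, rspo1, grna and grnb; points are arrays coloured by replicate, and bars give the mean and SD of 3 arrays. The phlda3 mean went from 1.55 at 16 hpf to 2.75 at 72 hpf, while grna replicates lay on both sides of 0 at each age.

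At 16 hpf, when somites are forming, few transcripts passed the test and nearly all were higher in the morphants. The largest rises were khdrbs1a, an RNA-binding protein gene, at a log2 ratio of 1.09, ldb1a, a cofactor of LIM-homeodomain factors, at 0.95, and mrpl20, a protein of the mitochondrial ribosome, at 0.92. They were followed by pggt1b at 0.91, acot9.2 at 0.90, vps26c at 0.87, ino80db at 0.84 and zdhhc5a at 0.82. The matrix metalloproteinase gene mmp2 rose by 0.61, and znf131, which encodes a zinc finger protein, fell by 0.60. Except for khdrbs1a, these rises belong to probes that were higher at all 4 ages, a candidate for a shared hybridisation signal. Adjusted p for these 10 genes lay between 0.0207 and 0.0438, and SDs over 3 arrays lay between 0.018 and 0.22. For khdrbs1a 1 of 2 probes passed, for ldb1a 1 of 3 and for znf131 1 of 2. None of the 10 kept its call when any 16 hpf array was left out, or with the Feature Extraction log ratio.

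In all 75 of 35932 probes passed at 16 hpf, 73 higher and 2 lower, and 65 of the higher ones lay in the top intensity quintile. Of the 73 higher probes 52 were higher at all 4 ages and may share a hybridisation signal, as the closing observations set out. The count of probes past the test at 16 hpf was 153 (143 higher, 10 lower) with the slide as a block and 748 (441 higher, 307 lower) with the files as attached. With the stage trend removed, that is each array's trend along the wild-type change with age, it was 45, all higher. The main count became 0, 4 and 0 without replicate 1, 2 or 3 of this age. No member of the p53 response list passed over all probes, but 6 of 23 did when adjusted over the list alone, all higher. Camera at a preset correlation called 6 lists at this age. The p53 response (median log2 ratio 0.17), the ribosomal proteins (0.23), the fore- and hindbrain regional genes (0.34), the epidermal genes (0.24) and the interferon and innate immune genes (0.15) were shifted up. The posterior hox genes were shifted down, with a median of -0.13 that was 0.44 under median centring. None of these shifts held with an estimated correlation (smallest adjusted p = 0.854) or with fry (smallest adjusted p at this age = 0.264). The brain and hox lists stood apart from each other between replicates: the brain list lay at 0.76, 0.04 and 0.49 and the hox list at -0.64, 0.61 and -0.27 for replicates 1, 2 and 3. The epidermal list lay at 0.69, -0.43 and 0.55 and the interferon list at 0.09, -0.05 and 0.50.

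Of 23 named calls at 24 hpf 15 were lost with the files as attached, among them phlda3, ccng1, rspo1 and lnx1. By the value table's link the files attached to 24 hpf are of 72, 16 and 24 hpf, so this loss can come from mixed ages. Among the largest rises at 24 hpf phlda3, which encodes an inhibitor of Akt signalling, rose by 2.49. The cyclin G1 gene ccng1 rose by 1.93 ± 0.21 (SE), a 3.82-fold change seen with 3 of 3 probes at an adjusted p of 0.00752. The Wnt agonist gene rspo1 rose by 2.73, the ubiquitin ligase gene lnx1 by 2.28, mat2al by 1.58, lyrm1 by 1.51 and the kinase gene vrk2 by 1.36. For lnx1 1 of 2 probes passed. The p53 response list had 4 of 23 members higher and none lower over all probes, and 11 higher when adjusted over the list alone. Its median was 0.38, at 0.48, 0.36 and 0.31 on the 3 arrays. The forkhead factor gene foxo3b rose by 1.16 with 1 of 2 probes, the other at 0.24, and mmp2 rose by 0.81.

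The falls at 24 hpf were smaller. The largest were caprin1a at -0.70 and rpl22l1, a ribosomal protein paralogue, at -0.66, then znf131 at -0.64, snrnp70, a component of the U1 splicing particle, at -0.63, khsrp at -0.54, coro1ca at -0.52 and rbbp5 at -0.52. For rpl22l1 both probes passed, and for the others 1 of 2 did. Under median centring in place of loess the values of khsrp, rbbp5, rpl22l1 and snrnp70 were above 0, from 0.09 to 0.19, and none of these falls stayed past the threshold. That setting leaves the trend along intensity in, so it does not test the falls. Of 72 ribosomal protein genes measured, 3 rose and 1 fell, with rpl8 at 0.72 and rps18 at 0.62, and 24 were higher and 2 lower when adjusted over the list alone. For rpl8 and rps18 1 of 2 probes passed. The list's median was 0.27.

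In all 159 probes passed at 24 hpf, 132 higher and 27 lower. With the slide as a block 455 did (308 higher and 147 lower), and with the files as attached 75 did (70 higher and 5 lower). The count was 1, 25 and 2 without replicate 1, 2 or 3 of this age. In the main fit 75 of the 132 higher and 16 of the 27 lower probes lay in the top intensity quintile. With the Feature Extraction log ratio 16 probes passed, all higher, and among the named genes ccng1, lnx1 and vrk2 kept their calls. Camera called 10 lists. The p53 response, ribosomal proteins, oxidative phosphorylation (median 0.21), glycolysis (0.12) and the interferon and innate immune genes (0.13) were shifted up. The liver genes (-0.39), neural progenitors and glia (-0.23), fore- and hindbrain genes (-0.18), hedgehog signalling (-0.14) and the cell cycle genes (-0.14) were shifted down. Under median centring the medians of the neural progenitor, hedgehog and cell cycle lists were 0.34, 0.30 and 0.40. The liver list lay at -0.72, 0.03 and -0.59 on the 3 arrays. None of the 10 held with an estimated correlation, where the smallest adjusted p was 0.854.

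Among the largest rises at 48 hpf were genes of the p53 pathway, at 2.53 for phlda3, 2.52 for mdm2, a ubiquitin ligase gene, 1.96 for bbc3, which encodes the cell death protein Puma and for which 1 of 2 probes passed, and 1.61 ± 0.21 (SE) for ccng1. Adjusted p was 0.00308 for ccng1. Of the 23 measured p53 response genes 6 rose, none fell and 17 did not pass, and 11 were higher when adjusted over the list alone. With the files as attached the calls of mdm2 and bbc3 were lost and those of phlda3 and ccng1 stayed. Beside them rspo1 rose by 2.61, the heat shock protein gene hspa1b by 2.36 and the transcriptional coregulator gene cited2 by 2.16. The hspa1b value rested on 3.98, 0.46 and 2.62 and that of cited2 on 2.58, 1.03 and 2.88 for replicates 1, 2 and 3, and both calls were lost when other arrays were left out and with the files as attached. The muscle protease gene capn3a, calpain 3, rose by 1.12, with 1.12, 1.21 and 1.02 on the 3 arrays, and kept its call with any array left out.

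Among the largest falls at 48 hpf the LIM-homeodomain gene lhx5 fell by 1.16, sox11b, a factor of neural progenitors, by 1.07, gdf11, a relative of myostatin, by 1.07, aldh2.1 by 0.97, rpl22l1 by 0.96, the chromatin protein gene hmgb1b by 0.89, the Wnt receptor gene fzd8a by 0.89 and dlb, a Delta ligand, by 0.88. For sox11b, fzd8a and rpl22l1 both of 2 probes passed, and for gdf11 and dlb 1 of 2 did. The sox11b and rpl22l1 calls held with any array left out. In the 12 fits that left 1 array out the calls of lhx5, hmgb1b and dlb held in 3, 5 and 8. These 3 calls were also lost with the Feature Extraction log ratio. Those of gdf11, aldh2.1 and fzd8a held in 9, 10 and 10 and stayed with that ratio. All 8 falls lost their call with the files as attached. Of 28 neuronal genes 2 fell, isl1a by 0.75 and elavl3 by 0.70, each with 1 of 2 probes, and 4 were lower when adjusted over the list alone. The isl1a call held in 2 and the elavl3 call in 10 of the 12 fits with 1 array left out. Both were lost with the Feature Extraction log ratio. None of 16 neural progenitor and glia genes passed over all probes, and 1 fell with the slide as a block. The stress factor gene xbp1 fell by 0.71, at 0.09 under median centring, where rpl22l1 read -0.05 and lost its call. The replication origin gene orc2 rose by 0.57 and mmp2 by 0.69. With the stage trend removed orc2 read 0.33 and lost its call (limma adjusted p = 0.116). Of the 72 ribosomal protein genes 6 rose, with rps18 and rpl8 at 0.67 each and 1 of 2 probes past the threshold, and rpl22l1 alone fell.

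In all 635 probes passed at 48 hpf, 521 higher and 114 lower. With the slide as a block 2518 did (1514 higher and 1004 lower), and with the files as attached 1035 did (900 higher and 135 lower). The count was 180, 1259 and 214 without replicate 1, 2 or 3 of this age. In the main fit 273 of the 521 higher and 35 of the 114 lower probes lay in the top intensity quintile. Camera called 10 lists. The p53 response (median 0.39), the ribosomal proteins (0.26), the heat shock and unfolded protein genes (0.45) and the erythroid genes (0.33) were shifted up. Shifted down were the neurons (-0.41), neural progenitors and glia (-0.37), liver (-0.52), pigment cells (-0.56), cardiac muscle (-0.997) and fast skeletal muscle (-0.35). With an estimated correlation none held (smallest adjusted p = 0.854). The shift up of the erythroid genes was also lost with the slide as a block (adjusted p = 0.0804). Under median centring the medians of the neural progenitor, liver and fast muscle lists were 0.21, 0.02 and 0.47. Replicate 3 carried much of the shifts down, with medians of -2.25 for cardiac and -0.93 for fast muscle, against 0.09 and -0.35 in replicate 1 and -0.74 and 0.02 in replicate 2. The heat shock list lay at 0.57, -0.21 and 0.37, so replicate 2 went the other way.

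Among the largest rises at 72 hpf were phlda3 at 2.75, mdm2 at 2.38, rspo1 at 2.36, cited2 at 2.00, pth1a, a parathyroid hormone gene, at 1.83, pdlim3b at 1.72 and ccng1 at 1.65 ± 0.21 (SE). Adjusted p was 0.00244 for ccng1 and 0.00275 for phlda3. Of 23 p53 response genes 7 rose, none fell and 16 did not pass, and 12 were higher when adjusted over the list alone. The cited2 value rested on 2.32, 0.43 and 3.26, and its call was lost without some arrays. The heat shock list had 3 of 29 members higher, among them the chaperone gene hsp90aa1.1 at 1.54 and the myosin chaperone gene unc45b at 1.06. The hsp90aa1.1 call held in 4 and the unc45b call in 11 of the 12 fits with 1 array left out. With the Feature Extraction log ratio and with the stage trend removed hsp90aa1.1 lost its call and unc45b kept it.

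The largest fall at 72 hpf was gc, the vitamin D binding protein gene, by 2.55. The glyoxylate transaminase genes agxtb and agxta fell by 2.37 and 2.27, the insulin gene ins by 2.33, the oxygenase gene cyp1c1 by 1.93, the fibrinogen gene fgb by 1.90, the natriuretic peptide gene nppa by 1.74 and the carboxylesterase gene ces2a by 1.60. For agxta the arrays read -1.22, -2.97 and -2.62, and both probes passed. For fgb they read -1.82, -1.71 and -2.17, with 3 of 3 probes. For gc and ins 1 of 2 probes passed and for nppa 2 of 3. The gc and agxtb values were uneven, with gc at -2.83, -0.36 and -4.46 and agxtb at -0.06, -4.29 and -2.77. The calls of agxta and fgb held with any array left out. With the files as attached those of gc, agxta, agxtb and ces2a were lost. Of 21 liver genes 3 fell, none rose and 9 were lower when adjusted over the list alone. Of 23 gut and pancreas genes 2 fell, ins and cpa5 at -0.61, and 1 rose, cela1.4 at 0.53. The cpa5 value was -0.07 (adjusted p = 0.768) once the stage trend was removed.

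Of 55 cell cycle and DNA replication genes 7 rose at 72 hpf and none fell, with ccnd1 at 0.92 (1 of 2 probes) and orc2 at 0.84, and 28 were higher when adjusted over the list alone. The ccnd1 call held in 3 and the orc2 call in 12 of the 12 fits with 1 array left out. With the Feature Extraction log ratio and with the stage trend removed ccnd1 lost its call and orc2 kept it. The list's median was 0.04, 0.68 and 0.37 for replicates 1, 2 and 3. Of 45 muscle atrophy and proteasome genes 6 rose, among them capn3a at 0.87 and the proteasome subunit gene psmc5 at 0.60, and ubc fell by 0.37, a value that was 0.56 under median centring. Of 42 lysosomal genes 2 fell, the autophagosome gene map1lc3b by 0.74 and lamp1a by 0.57, both slightly above 0 under median centring at 0.03 and 0.19. Among ribosomal protein genes rpl7l1 rose by 0.60 and rps18 by 0.52 (1 of 2 probes), while rpl22l1 stood at 0.467-fold of wild type and rps9 fell by 0.68. Under median centring rps9 read 0.32, and rpl22l1 read -0.16 and lost its call.

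Single members of other lists passed at 72 hpf. The neuronal genes elavl4 and sypb fell by 0.98 and 0.78, with 1 of 3 and 1 of 2 probes past the threshold, and the purine synthesis gene paics, listed with pigment cells, fell by 0.65. The epidermal factor gene tp63 fell by 0.43, the receptor gene egfra by 0.59 and the enolase gene eno1b by 0.50. For tp63, egfra and eno1b 1 of 2 probes passed. Under median centring paics, tp63, egfra and eno1b read 0.0028, 0.20, 0.05 and 0.09. The lens gene crygn2 rose by 0.86 and mmp2 by 0.76. Of the 12 fits that left 1 array out, eno1b kept its call in 0, tp63 and elavl4 in 1 and crygn2 in 4. The calls of paics, egfra and sypb stayed in 10 and that of mmp2 in 12. With the Feature Extraction log ratio elavl4, paics, tp63, egfra and eno1b lost their calls. Removal of the stage trend took the calls of the same genes and of crygn2 (limma adjusted p = 0.119).

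In all 1738 probes passed at 72 hpf, 1220 higher and 518 lower. With the slide as a block 3604 did (2115 higher and 1489 lower), and with the files as attached 6166 did (3010 higher and 3156 lower). With the stage trend removed 809 did (585 higher and 224 lower). The count was 1576, 644 and 602 without replicate 1, 2 or 3 of this age. In the main fit 701 of the 1220 higher and 169 of the 518 lower probes lay in the top intensity quintile. With the Feature Extraction log ratio 900 passed, 728 of them higher and 172 lower. Camera called 14 lists, and 7 with the stage trend removed. Shifted up were the p53 response (median 0.41), cell cycle (0.37), muscle atrophy and proteasome (0.28) and heat shock genes (0.45). Shifted down were liver (-0.92), gut and pancreas (-0.41), neurons (-0.42), pigment cells (-0.61), cardiac muscle (-0.62), fast skeletal muscle (-0.35), lysosome (-0.16), growth factor and myostatin signalling (-0.06), oxidative phosphorylation (-0.17) and glycolysis (-0.22). With an estimated correlation none held (smallest adjusted p = 0.854). Under median centring the medians were 0.09 for neurons, 0.56 for fast muscle, 0.43 for lysosome, 0.72 for oxidative phosphorylation and 0.38 for glycolysis. The oxidative phosphorylation list lay above 0 in replicate 2 (0.08) and the lysosome list in replicate 1 (0.03).

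**Figure D2:**
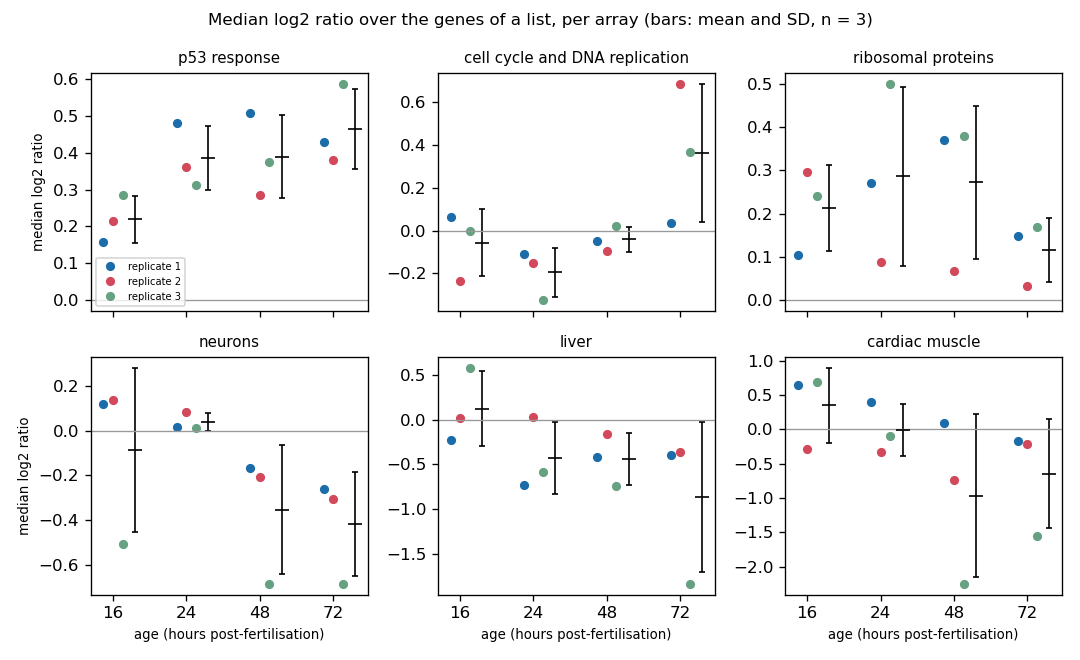
Median log2 ratio of morphant over wild type over the genes of 6 lists on each array (vertical axis) against age in hpf (horizontal axis); points are arrays coloured by replicate, and bars give the mean and SD of 3 arrays. The p53 response median lay above 0 on all 12 arrays, and the liver median at 72 hpf ran from -0.36 in replicate 2 to -1.84 in replicate 3.

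None of 22 measured myogenic regulators and progenitor genes, 30 fast muscle genes or 9 slow muscle genes passed at any age over all probes. With the slide as a block 1 myogenic and 1 slow muscle gene were higher at 48 hpf, and 1 fast and 1 slow muscle gene were lower at 72 hpf. As a list the fast muscle genes were shifted down by camera at 48 hpf (adjusted p = 0.00359) and 72 hpf (adjusted p = 0.0223). Neither shift held with an estimated correlation (adjusted p = 0.920 at both ages) or with fry (0.658 and 0.743). When adjusted over the list alone, 1 slow muscle gene was lower at 72 hpf. The fast muscle median lay at -0.35 in replicate 1, 0.02 in replicate 2 and -0.93 in replicate 3 at 48 hpf, and at 0.01, -0.12 and -0.89 at 72 hpf. Among 12 cardiac genes nppa alone fell over all probes, at 72 hpf. With the slide as a block 2 were lower at 48 hpf and 1 at 72 hpf, and 1 was lower at each of these ages when adjusted over the list alone. The lists of myogenic regulators, slow muscle, notochord and cartilage, myeloid cells, endothelium, kidney, eye and lens, and collagens and extracellular matrix were not shifted at any age by camera at the preset correlation. By camera the somitogenesis list was not called without the block, with an adjusted p of 0.0503 at 48 hpf. It was shifted up at that age with the slide as a block (adjusted p = 0.0116), which leaves the spread between slides out of the error. With an estimated correlation its adjusted p at 48 hpf was 0.920, and with fry 0.603, both without the block.

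Whether the effect of the knockdown changed with age was tested on the ratios themselves. With limma no probe passed the F test across the 4 ages, where the smallest adjusted p was 0.0529 and 2455 of 35932 probes had an unadjusted p under 0.05. No probe differed between 16 and 24, between 24 and 48 or between 48 and 72 hpf either, with 632, 1550 and 1472 at an unadjusted p under 0.05. The slide block also gave 0 in each case. Array weights gave 70 probes past the F test, a random slide block 26 and the mean of a gene's probes 3. The step in p53 response genes between 16 and 24 hpf was therefore not called for any probe, and the list difference is given in the closing observations.

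Calls recurred across ages. Probes called at both 48 and 72 hpf numbered 443, all in the same direction, with 395 higher and 48 lower against 17.7 and 1.64 for independent lists. Between 16 and 24 hpf 56 were shared, 54 higher and 2 lower, against 0.268 and 0.0015. Between 24 and 48 hpf 122 were shared, 112 higher and 10 lower, against 1.91 and 0.0857. In all 472 probes were called in the same direction at 2 or more ages. At all 4 ages 52 probes were higher and 1 was lower. Among the higher ones, chosen by the size of their smallest change, were ldb1a with 0.95, 0.90, 1.06 and 0.97 at 16, 24, 48 and 72 hpf (1 of 3 probes), mrpl20 with 0.92, 0.84, 1.11 and 0.87, acot9.2, pggt1b and vps26c. The lower gene was znf131, with 1 of 2 probes. Under median centring, which leaves the trend along intensity in, it read -0.05, -0.13, -0.04 and -0.06 and lost its call at each age. A dye effect that recurs on every array, or arrays of the same slide, would also give shared calls. The 4 ages also share an estimate of each probe's spread, so their calls are not independent. Fits to the arrays of an age alone called 0, 2, 0 and 0 probes.

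The question whether morphants lagged in stage was addressed by setting their ratios against the wild-type change with age. Across 11175 genes, which are not independent replicates, the ratio at 48 hpf correlated at r = -0.41 with the wild-type change from 24 to 72 hpf. Genes that rise with age were lower in the morphants and genes that fall with age were higher. The ratio at 24 hpf correlated at r = 0.02 with the wild-type change from 16 to 48 hpf. By array the values at 48 hpf were -0.32, 0.04 and -0.50 for replicates 1, 2 and 3, and at 24 hpf -0.25, 0.40 and -0.11. Without replicate 3 of 48 hpf r was -0.22, and with the files as attached it was -0.28.

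**Figure D3:**
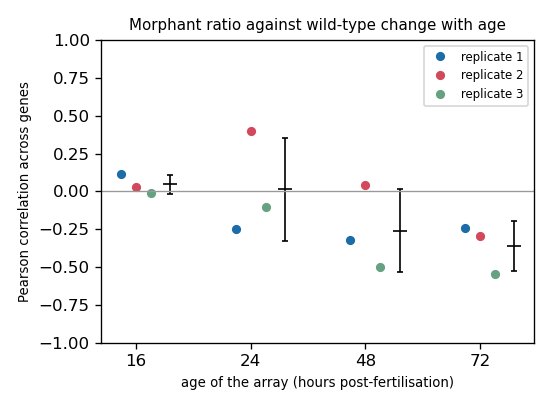
Pearson correlation across genes (vertical axis) between each array's log2 ratio and the change with age in wild type from arrays of other ages, against the age of the array in hpf (horizontal axis); points are arrays coloured by replicate, and bars give the mean and SD of 3 arrays. The wild-type change ran from 24 to 48 hpf for arrays of 16 and 72 hpf, from 16 to 48 hpf for 24 hpf and from 24 to 72 hpf for 48 hpf. At 72 hpf the 3 arrays lay at -0.24, -0.29 and -0.55.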

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

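The list differences, the dye test, the tests on other probes of a gene, on probes of like intensity and on a shared signal, the dissection and stage tests and the splits for differences between ages were chosen only after the result was seen.

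What set these lists apart is that their shift differed between neighbouring ages by camera at a preset correlation, with and without the slide block, in 25 of 93 tests. None of them held with an estimated correlation, where the smallest adjusted p was 0.799, or 0.238 with the block as well. Between 16 and 24 hpf the median change in log2 ratio was 0.17 for the p53 response (adjusted p = 5.14e-05), 0.14 for oxidative phosphorylation and 0.15 for glycolysis. Over the same step it was -0.49 for fore- and hindbrain genes, -0.57 for liver, -0.12 for neural progenitors and glia and -0.11 for the cell cycle. Between 24 and 48 hpf it was -0.58 for fast skeletal muscle, -0.68 for cardiac muscle, -0.38 for neurons, -0.10 for gut and pancreas, -0.27 for kidney, -0.40 for pigment cells, -0.26 for oxidative phosphorylation and -0.40 for glycolysis. It was 0.26 for fore- and hindbrain genes, 0.27 for somitogenesis, 0.23 for heat shock and 0.14 for the cell cycle. Between 48 and 72 hpf it was 0.41 for the cell cycle and 0.31 for muscle atrophy and proteasome, and -0.44 for liver, -0.14 for lysosome, -0.14 for oxidative phosphorylation and -0.16 for ribosomal proteins.

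The p53 response genes were higher at 24, 48 and 72 hpf, with 17 calls of 10 list members. After each array's trend along the wild-type change with age was removed 14 of the 17 calls stayed. The removal takes out only a linear trend fitted over all genes, which on average was nearly flat at 24 hpf. Large ratios can outlast it whatever their cause, so it does not decide whether a stage difference gave the rise. A dye bias of constant size stays open: the 10 members' mean ratio over the later ages exceeded that at 16 hpf by 0.61 ± 0.46 (SD over 3 slides), with 0.30 on the lowest slide and 1.14 on the highest. These 10 were chosen by their later calls, and for the median of all 23 members the excess was 0.19 ± 0.10. As a hypothesis, the rise may be a response to loss of progranulin A or a response to the morpholino itself, and without a control morpholino arm these were not told apart by any test here.

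The 52 probes higher at all 4 ages are a candidate for a shared hybridisation signal in place of 52 changed transcripts. Of the 17 named genes 8 have further tested probes: in 7 genes none of the 13 further probes was called at any age, while both vps26c probes are among the 52, and the median over these 15 was -0.0056, against 0.82 for the 52. The median correlation between the 52 probes' deviations from the age means was 0.84, above the highest of 1000 random sets of like intensity at 0.17. The 52 were chosen by their calls in these same data and the random sets by intensity alone. Transcripts that change together, or the structure by slide, may also give such a correlation. It therefore does not tell a shared signal from 52 changed transcripts. The count of 5131 probes higher at all 4 ages with median centring says nothing on loess, contrary to the bound set beforehand, as this setting alone raised the top intensity quintile by a median of 0.62. With median centring the 52 stood 0.73 ± 0.21 (SD over 12 arrays) above probes of like intensity, with 0.36 on the lowest array. With loess the excess was 0.74 ± 0.19. The excess was thus present without loess. Loess shifts probes of like intensity alike, so the comparison was bound to come out this way and does not test loess. A sequence difference between the embryos, cross-hybridisation to an abundant RNA and a dye effect may each give this picture. They were not separated from each other or, for genes without further probes, from changed transcripts.

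At 48 and 72 hpf genes that rise with age in wild type were lower in the morphants. The correlation was r = -0.41 at 48 hpf against the wild-type change from 24 to 72 hpf. At 72 hpf it was -0.52 against the change from 24 to 48 hpf. The spans differ, so these values do not show a growth with age. The design fixed before the data were examined named only the correlations at 48 and 24 hpf. A difference in dissection level stays open: the brain list minus the posterior hox list came to 0.067 ± 0.16 (SD) over the 6 arrays of these ages, but members of both lists went both ways, and the cardiac (-0.997 and -0.62) and liver (-0.52 and -0.92) medians were lower. The somitogenesis genes had a median above 0 on 6 of the 6 arrays, from 0.01 to 0.53, but they fall with age in wild type, so this repeats the pattern and does not test whether morphants were younger in stage than their wild type. Whether the knockdown slows development or the clutches were staged differently was not tested, and r = 0.04 in replicate 2 at 48 hpf leaves the size open at that age.

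Other groupings of the arrays were counted for each model. With 3 arrays at an age there are 4 sign patterns, too few for a share under 0.05, and 1 of the 4, the real one, reached the real count of calls. That held at 16 hpf (75 probes, highest other 12), at 24 hpf (159 and 0), at 48 hpf (635 and 0) and at 72 hpf (1738 and 0). For gene lists 4, 2, 3 and 2 of the 4 patterns gave as many as the real 6, 10, 10 and 14, with 17, 10, 11 and 14 as the highest of the others. The F test called 0 probes, a count that any split reaches (100 of 100 random ones), so the tally says nothing about chance. The highest other split called 378 probes. The arrays do hold a structure by slide, as 12 of 12 correlated best in their deviations with an array of their own number. Whether this gave the 378 calls was not tested. For each neighbouring difference the real count was also 0, which 10 of the 10 splits of 6 arrays reach of necessity, with 0, 0 and 327 probes as the highest of the others.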

How the results depend on the processing

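The files as attached to samples, removal of the stage trend, leaving out all 4 arrays of a replicate number and camera on differences between ages were chosen after seeing the data. Where a count moved, the cause was not tested unless the setting itself changes the number of arrays or genes. The counts of changed probes depended strongly on the setting, and the 3 arrays of an age and the lower share of probes above background on replicate 1 limit the precision. Counts are given in the order 16, 24, 48 and 72 hpf. The main ones were 75, 159, 635 and 1738, with 472 calls shared between ages in the same direction and 0 probes in the F test.

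With the files as attached the counts were 748, 75, 1035 and 6166, of which 59.0, 93.3, 87.0 and 48.8 percent were higher. By the value table's link these attached groups mix ages. With the Feature Extraction log ratio they were 0, 16, 328 and 900, with 244 shared calls, and the value table gave 0, 16, 328 and 902, with 244 shared. A normexp offset of 16 gave 28 at 16 hpf and 73 at 24 hpf. Median centring in place of loess gave 13617, 12649, 13309 and 15164, with 15446 shared calls, and moved the median of all tested probes to between 0.17 and 0.21. Of the probes called, 70.7, 67.3, 72.7 and 73.6 percent were higher, where with loess 73 of 75, 132 of 159, 521 of 635 and 1220 of 1738 were. Scaling between arrays gave 202 at 16 hpf, 279 at 24 hpf and 1 probe in the F test, and no filter on dim probes gave 5 in the F test.

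The mean of a gene's probes gave 4, 29, 174 and 758, with 130 shared and 3 genes in the F test. Fits to the arrays of an age alone gave 0, 2, 0 and 0, with 0 shared. A trended robust variance gave 0, 0, 0 and 852, with 0 shared. Array weights gave 521, 6430 and 1001 at 24, 48 and 72 hpf, 70 in the F test and 1009 shared. A log2 ratio of at least 1 left 4, 31, 121 and 199, with 39 shared, and treat against 1.5-fold left 0, 0, 0 and 3, with 0 shared. After the stage trend was removed 45 passed at 16 hpf, 809 at 72 hpf, and 7 gene lists were shifted at 72 hpf.

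With the replicate block, which is also the slide as a fixed block, 153, 455, 2518 and 3604 probes passed, with 1388 shared calls. This block leaves the spread between slides out of the error of the age means. The slide as a random block gave 91, 178, 659 and 1723, with 26 in the F test. Same-numbered arrays correlated in their deviations from the age means at -0.03 to 0.73, over 0.1 in 14 of 18 pairs, and 12 of 12 arrays correlated best with an array of their own number. The labels give only the number. All 118 named values kept their side of the threshold with the block. The planned comparison of ages within 1 slide was not run as a test, since a slide holds 1 array per age.

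Without replicate 1 at all ages the counts were 0, 0, 0 and 0, with 0 shared. Without replicate 2 they were 2, 11, 1761 and 654, with 9 in the F test, 5 between 24 and 48 hpf, 2 between 48 and 72 hpf and 12 gene lists at 16 hpf. Without replicate 3 they were 0, 0, 0 and 318, with 0 shared and 11 gene lists at 16 hpf. Leaving out 1 array at a time gave 0 to 132 probes at 16 hpf, 1 to 214 at 24 hpf, 180 to 1259 at 48 hpf and 602 to 1687 at 72 hpf. It gave 0 to 21 in the F test, 0 to 3 between 16 and 24 hpf, 0 to 10 between 24 and 48 hpf, 0 to 8 between 48 and 72 hpf and 226 to 562 shared calls. Shifted gene lists ranged over 5 to 12, 9 to 11, 7 to 12 and 9 to 15 at the 4 ages. The correlation with the wild-type change ranged from -0.46 to -0.22 at 48 hpf and from -0.19 to 0.16 at 24 hpf.

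Camera with an estimated correlation and fry each called 0, 0, 0 and 0 lists, against 6, 10, 10 and 14 at the preset correlation.

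Of 106 named values past the threshold, 10 of 29 at 48 hpf and 14 of 44 at 72 hpf kept their call with each array left out, against 0 of 10 at 16 hpf and 0 of 23 at 24 hpf. With the Feature Extraction log ratio 59 of the 106 lost the call. With the files as attached 1 of 10, 15 of 23, 16 of 29 and 18 of 44 lost it at the 4 ages, and grna, the target, gained a call at 72 hpf, at -1.03 in place of -0.30. By the value table's link the files behind that grna value are replicate 3 of 24, 48 and 72 hpf. After the stage trend was removed 3 of 10, 4 of 23, 1 of 29 and 15 of 44 lost it at the 4 ages. At 72 hpf cpa5 then read -0.066 in place of -0.61 and eno1b -0.13 in place of -0.50, while agxtb read -1.83, nppa -1.34 and ces2a -1.22. Only median centring, among the settings run, turned signs, and as it leaves the trend along intensity in, these turns do not test the falls. At 24 hpf khsrp then read 0.18, rbbp5 0.085, rpl22l1 0.19 and snrnp70 0.091, and at 48 hpf xbp1 read 0.087. At 72 hpf egfra read 0.052, eno1b 0.086, lamp1a 0.19, map1lc3b 0.025, paics 0.0028, rps9 0.32, tp63 0.20 and ubc 0.56.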

Other observations

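At 16 hpf the replicates lay apart in regional and tissue lists. The fore- and hindbrain median was 0.76, 0.04 and 0.49 on the log2 scale for replicates 1, 2 and 3, and the posterior hox median was -0.64, 0.61 and -0.27. Cardiac genes had medians of 0.65, -0.28 and 0.69. In wild type the fast muscle list rose from 9.95 ± 1.12 at 16 hpf to 14.83 ± 0.23 at 24 hpf and 16.73 ± 0.26 at 48 hpf (SD, n = 3).

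Of 3 muscle and mesoderm genes singled out after their values were seen, none passed the test at 48 hpf by limma. The log2 ratio was 1.66 for myog (adjusted p = 0.154), 2.02 for the paraxial mesoderm gene tbx6 (adjusted p = 0.0833) and -2.62 for the heart gene myl7 (adjusted p = 0.197).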
